A study of Gallus gallus with 3 samples.

How the data were processed

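Breast muscle of male Arbor Acres broilers, a fast-growing meat chicken (Gallus gallus), was sequenced at 42 days of age after exposure to 50 ± 3 ppm of atmospheric ammonia. Per the labels' protocols, total RNA was isolated with TRIzol, mRNA was taken with oligo(dT) beads, and standard Illumina libraries were made. The 3 libraries used here form 1 group and are called library 1, 2 and 3 after the number in their titles. No library of another exposure was used here, so no contrast between exposures was made and no value below measures an effect of ammonia. The labels do not say that the 3 libraries came from separate birds, so every SD and p-value measures only the spread between these libraries, which may be technical.

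Each library came with 1 table of 36977 RefSeq transcripts and 1 value per transcript. The unit of the deposited values is not named in the tables. They were treated as FPKM (fragments per kilobase of transcript, scaled to the size of the library), which is an inference from the deposited values. They are not whole numbers, their totals were 569361, 586193 and 573648, and 4247 to 4370 values per library lay between 0 and 0.001, as estimators that divide reads between isoforms can give. TPM values with some transcripts left out would give the same ratios within a library. The submitters' processing notes name CASAVA 1.7, Bowtie2 and HTSeq, with no role for each. The genome build, the annotation and the program that made the values are not given in the sources used here.

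Read depth is unknown, so no counting interval or detection floor is given. Whole reads could not be recovered: among 214 low transcripts, at most 2 shared the same ratio between libraries 1 and 2, rounded to 3 decimals of the natural log. Several globin transcripts, abundant in any tissue that holds blood, were listed near 0 beside a well detected one, so a value at or near 0 can be a failed estimate.

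Transcripts were paired with genes through an NCBI RefSeq gene table of assembly GRCg7b, used for names only. Accessions were matched without their version, since only 1013 matched with it. In all, 13188 of 36977 transcripts (35.7%) matched, giving 10663 genes, of which 9078 had 1 transcript. Among curated NM transcripts 5364 of 5726 matched, and among predicted XM transcripts 7195 of 26401. A gene's value is the sum over its matched transcripts. Named genes held 73.4%, 75.6% and 75.7% of the summed value of libraries 1 to 3. The other 23789 transcripts carry no name here and entered only the library totals and the counts of transcripts. Genes with near-identical copies, such as the MYH1 myosins and the actins, can share reads, and their split is uncertain.

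The lists of genes, the pairs of related forms, the tests and the rule for named genes were fixed before the data were examined. The test planned for the spread of single genes needed read counts. Since the tables hold none, its planned substitute for normalized values was used. Genes with at least 1 FPKM in at least 2 libraries were kept (6595 genes) and taken as log2(FPKM + 1), a scale that understates differences of low genes. The variance of each gene over 3 libraries was set against its trend with mean level in limma 3.58.1 (R 4.3.3, robust fit, residual df 2), with the upper F tail and Benjamini-Hochberg adjusted p under 0.05 as the call.

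For 35 lists with 654 members, 483 members were matched, 18 of them through a synonym. After the matches were seen, a synonym that led to another fixed member was no longer counted. This kept CASQ1 from entering as CASQ2, and some members still enter under a related name, such as ALAS2 as ALAS1. For each list with at least 5 genes kept, the median log2 deviation of 1 library from the mean of the other 2 was ranked among 10000 random lists of the same size, matched in 20 bins of mean level. A list was said to stand apart where its percentile was under 0.5 or over 99.5. The median SD of log2 level was ranked in the same way. Relative deviations are the list's median minus that of the random lists. These percentiles describe the 3 libraries and are not p-values, since genes are not replicates and genes regulated together move together. The deviations of the 3 libraries are tied, so 1 library out of place moves the other 2 the opposite way. Each call was therefore also checked against each of the other 2 libraries singly.

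Pairs of related gene forms were compared within each library as log2 ratios of FPKM. A ratio was called where all 3 libraries lay on 1 side and the mean exceeded 2 SD, with an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25. Shares are percent of a library's summed value, given as mean ± SD over 3 libraries. Genes named in the text were the 15 with the highest mean, the 2 highest members of each list, the member with the largest SD of log2 level among those with a mean of at least 5 FPKM, both genes of each pair, and every gene kept from a list with 5 or fewer. Other genes named are said to have been chosen after their values were seen.

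The spread test was tried on simulated data with the real genes' means and spread. The list percentiles were tried on random lists of the real genes. Without added differences, 0 of 6595 genes were called. The spread test was then run on a first mixture of 200 shifted genes, 50 each with log2 shifts of 2, 4, 6 and 8 in 1 library, and called 0 of 50 at every size. After that result was seen, a second mixture with shifts of 2, 4, 8 and 14 was run. It called 0, 0, 35 and 32 of 50, and 1 of 6395 unshifted genes. The calls at a shift of 8 thus differed between the 2 mixtures, and the cause was not tested. At shifts of 6 or less the test called none in either mixture. For the list percentiles, 3 of 600 combinations of an unshifted random list of 15 genes with a library stood apart. So did 2 of 200 such lists for spread, and 44 of 50 lists shifted by a log2 of 0.5. Each was ranked among 1000 random lists. Counts for random genes do not give the rate of calls for genes regulated together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives were other filters, pseudocounts, bins, scalings between libraries, curated transcripts only, single transcripts, and each library left out in turn.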

Results

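The data describe the breast muscle transcriptome of 42-day-old male broilers kept at 50 ± 3 ppm of atmospheric ammonia, in 3 libraries of 1 group. Values above 0 were listed for 9018, 9057 and 8877 named genes in libraries 1, 2 and 3, and for 8594 genes in all 3. At least 1 FPKM was reached by 6706, 6611 and 6447 named genes, and by 6157 in all 3. Read depth is unknown. Across genes, log2 levels of libraries 2 and 3 had a Pearson correlation of 0.973, against 0.951 for library 1 with library 2 and 0.951 for library 1 with library 3. Genes are not independent replicates. More than 2-fold differences on the log2(FPKM + 1) scale separated 538 genes between libraries 1 and 2, 586 between libraries 1 and 3, and 259 between libraries 2 and 3. The median gene deviated from the mean of the other 2 libraries by 0.15, -0.04 and -0.09 log2 in libraries 1 to 3, and the list values below are relative to matched genes.

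The first question was which genes the tissue expressed most. GAPDH, a glycolytic enzyme, had the highest mean among named genes at 21011 ± 3925 FPKM (SD, n = 3). It was followed by parts of the contractile apparatus: the myosin light chain MYL1 at 15976 ± 2880 FPKM, the fast troponin T gene TNNT3 at 15641 ± 3595 FPKM, TNNC2 (fast troponin C) at 14413 ± 764 FPKM and TNNC1 (slow and cardiac troponin C) at 13403 ± 149 FPKM. LDHA, which reduces pyruvate to lactate, stood at 12426 ± 1650 FPKM, TNNI2 at 11803 ± 1832 FPKM and the tropomyosin TPM1 at 11363 ± 1180 FPKM. Next came PKLR, the name the gene table gives to a gene with the synonym PKM, at 7310 ± 1101 FPKM, and TPI1 at 6947 ± 705 FPKM. The rest of the 15 highest were TPT1, PGK2 (synonym PGK1), PGAM1, the translation factor EEF1A2 and AK1, with means of 5230, 5176, 4990, 3798 and 3593 FPKM. Together the 15 genes held 26.5 ± 2.17% of the summed value. Unnamed transcripts also reached high levels, the highest a mean of 20917 FPKM, so this order holds among named genes.

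The fixed gene groups divided that expression unevenly. Fast fibre contractile genes held 12.6 ± 1.53% of the summed value and glycolysis genes 11.6 ± 1.33%. Shares of lists, here and below, count matched members only, 9 of 13 for the fast list and 14 of 17 for glycolysis. They are lower bounds, and lists with near shares cannot be ranked. Cytosolic ribosomal protein genes held 6.27 ± 0.883%, led by RPLP1 at 2303 ± 485 FPKM and RPS10 at 2247 ± 381 FPKM. Slow fibre contractile genes held 2.61 ± 0.018%, most of it TNNC1. Nuclear genes of oxidative phosphorylation held 1.18 ± 0.258%, oxidative stress defence genes 0.916 ± 0.154% and heat shock genes 0.876 ± 0.133%. Genes of ammonia and amino acid nitrogen metabolism held 0.252 ± 0.015%. Their highest member was ADSL, of purine synthesis and the purine nucleotide cycle, at 600.1 ± 131 FPKM, followed by the aspartate aminotransferase gene GOT2 at 269 ± 53.8 FPKM. OTC, of the urea cycle, chosen after its values were seen, was listed at 0 in every library. All lists together, with 392 different genes, held 39.1 ± 2.76%. No test was applied to these shares.

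Markers of other cell types were present at low levels. Macrophage and monocyte genes held 0.054 ± 0.022% of the summed value, fibroblast genes 0.116 ± 0.040%, adipocyte genes 0.039 ± 0.017%, endothelial genes 0.015 ± 0.004% and red blood cell genes 0.049 ± 0.030%. Lymphocyte genes held 0.002 ± 0.001%, heterophil genes 0.008 ± 0.005%, smooth muscle genes 0.015 ± 0.002% and nerve genes 0.009 ± 0.001%. Too few genes of each of these lists, and of the red blood cell list, passed the filter for a percentile. Among red blood cell genes, HBBA was listed at 24.3, 54.1 and 98.7 FPKM and CA2 at 45.7, 355 and 189 FPKM in libraries 1 to 3. Of the W chromosome list, a check of the male label, HINTW, also chosen after its values were seen, was listed at 0 in every library. The highest of 4 matched genes, UBAP2L2, which entered through a synonym, had a mean of 0.346 FPKM. No mitochondrially encoded gene was matched.

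The second comparison set fast against slow or alternative forms of the same protein within each library. TNNI2 (fast troponin I) exceeded TNNI1 (slow troponin I) by a mean log2 ratio of 11.56 ± 1.76 (SD, n = 3). TNNI1 was listed at 1.49, 17.1 and 2.28 FPKM in libraries 1 to 3, and without library 2 the mean ratio was 12.57. TPM1 exceeded TPM3, the slow tropomyosin, by 8.32 ± 0.25, and LDHA exceeded LDHB, the form of oxidative tissue, by 8.66 ± 0.76. For hexokinase the second form was the higher: HK2 lay at a log2 ratio of -2.89 ± 0.48 to HK1. TNNC2 and TNNC1 were nearly equal, at 0.10 ± 0.06. Of 16 fixed pairs 5 were measured in every library, and 4 of these had all 3 libraries on 1 side and a mean above 2 SD. The exact sign-flip permutation p (two-sided) was 0.25 for each of the 5, the smallest that 3 libraries allow, so no ratio passed a 0.05 threshold. For 10 pairs a gene was not matched, and MYL3, of the pair with MYL1, was listed at 0 in library 1. Without library 3, the ratio of TNNC2 to TNNC1 also met the rule, and 5 ratios were called.

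**Figure D1:**
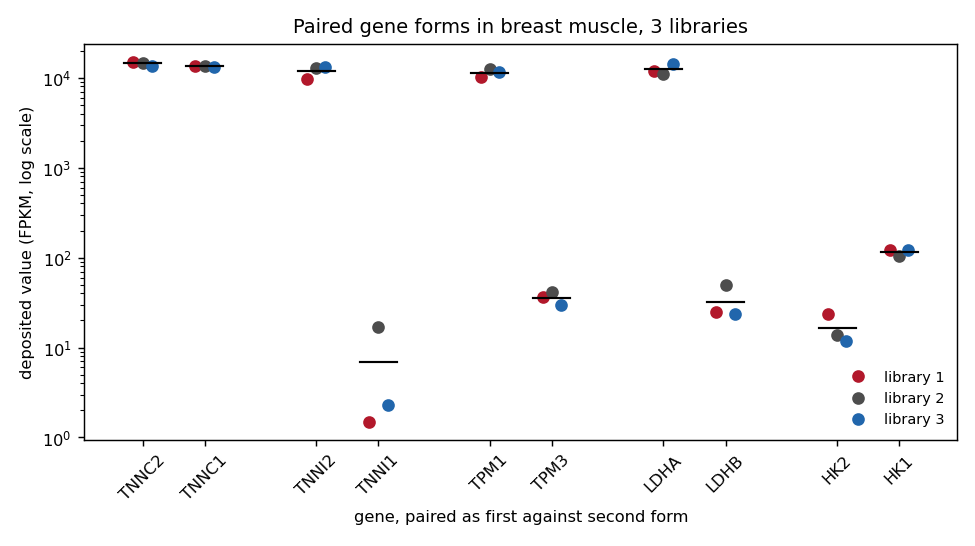
Deposited values (FPKM, log scale) of 5 pairs of gene forms in the 3 libraries, with the first form of each pair on the left, points for single libraries and bars for their mean. TNNC2 and TNNC1 lie side by side near their means of 14413 and 13403 FPKM, while TNNI1, TPM3 and LDHB lie far below TNNI2, TPM1 and LDHA.

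The third comparison asked whether single genes varied between libraries more than genes of similar level. None did after adjustment. The limma variance test called 0 of 6595 genes, with a smallest Benjamini-Hochberg adjusted p of 0.584. An unadjusted p under 0.05 was reached by 372 genes, where 330 would be if no gene had excess spread. That reference is too high where some genes differ, since the trend is fitted to all genes. In the first simulated mixture, 3.14% of unshifted genes lay under 0.05. These counts thus do not measure how many genes varied. On simulated data this test called none of the genes shifted by a log2 of 2 or 4 in 1 library, so the count of 0 does not show that the genes varied alike. The genes of largest spread, chosen after their values were seen, included CA3A, of the carbonic anhydrase family, with 2.11 FPKM in library 1 and 254 FPKM in library 2. SOCS3, an inhibitor of cytokine signalling, was listed at 52.5, 4.38 and 2.62 FPKM in libraries 1 to 3. FKBP5, a chaperone partner induced by glucocorticoids, was listed at 76.0, 7.63 and 8.97 FPKM, and INSIG1, a regulator of sterol synthesis, at 40.7, 300 and 455 FPKM. The fast myosin MYH1A, which can share reads with its copies, was listed at 4.77, 216 and 35.4 FPKM. Without library 2 the test called 31 genes, and without library 3 it called 6.

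The fourth comparison asked which gene groups stood apart in 1 library. Of 84 combinations of 28 lists and 3 libraries, 24 stood apart, in 13 lists, where 0.84 would by chance if genes were independent. Of the 24, 12 also stood apart from each of the other 2 libraries singly: 5 of 8 in library 1, 1 of 6 in library 2 and 6 of 10 in library 3. The combinations are not independent of each other, and lists share members: 4 genes of the fibroblast list are also in the extracellular matrix list. The labels give nothing that tells the libraries apart, so these values describe the libraries only.

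Library 1 was set apart by high immediate early and clock genes and by low cell division and matrix genes. Immediate early genes, transcribed within minutes of a stimulus, lay at a relative log2 deviation of 1.25, with 8 of 10 genes highest in library 1. BTG2 was listed at 205, 84.1 and 72.4 FPKM in libraries 1 to 3, JUN at 59.1, 45.2 and 21.0 FPKM and FOS at 54.0, 10.5 and 6.83 FPKM. Circadian clock genes lay at 1.09, with 6 of 8 highest in library 1. BHLHE40 was listed at 129, 59.7 and 41.3 FPKM, CRY1 at 62.3, 24.4 and 32.9 FPKM, and NFIL3 at 44.4, 9.13 and 11.6 FPKM. Both lists also stood apart from each of the other 2 libraries singly.

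Cell division genes lay at a relative log2 deviation of -1.26 in library 1, with 11 of 12 genes lowest there. CCNA2, a cyclin, was listed at 3.70, 5.45 and 8.44 FPKM, and CCNB1, which entered the list through a synonym, at 2.0, 7.13 and 7.29 FPKM. The exception was PCNA, a replication clamp, at 33.8, 24.2 and 29.9 FPKM. The list also stood apart upward in library 2 (0.49) and library 3 (0.73), but without library 1 these values were -0.06 and 0.06, while library 2 lay at 1.14 without library 3 and library 3 at 1.29 without library 2. With pseudocount 0.1 the 3 values were -2.42, 1.02 and 1.18. Extracellular matrix genes lay at -0.51 in library 1, with 14 of 19 genes lowest there. SPARC, a collagen-binding matrix protein, was listed at 200.5, 590 and 525 FPKM, and COL3A1 at 168, 409 and 307 FPKM. The list stood apart upward in library 2 (0.32) and library 3 (0.25). The call of library 3 was lost with pseudocount 0.1 (percentile 99.4) and with curated transcripts only (0.23, percentile 99.3). Without library 1 neither call held, with 0.17 for library 2 and -0.17 for library 3, while library 2 lay at 0.60 without library 3 and library 3 at 0.50 without library 2.

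The nuclear genes of oxidative phosphorylation lay at relative log2 deviations of -0.50, 0.02 and 0.44 in libraries 1 to 3, with 24 of 28 genes lowest in library 1 and 27 of 28 highest in library 3. COX7C, a subunit of cytochrome c oxidase, was listed at 653, 822 and 955 FPKM, and CYCS, cytochrome c, at 76.9, 172 and 295 FPKM. The calls of libraries 1 and 3 both stood against each other library singly. Citrate cycle genes lay at -0.22 in library 1 and -0.21 in library 2, where they did not stand apart, and at 0.38 in library 3, with 14 of 16 genes highest there, and at 0.25 with curated transcripts only, where percentile 99.2 no longer made a call. MDH2, a mitochondrial malate dehydrogenase, was listed at 279, 435 and 571 FPKM and IDH3A at 49.1, 96.1 and 150.3 FPKM. Fatty acid uptake and oxidation genes did not stand apart and went the other way, at 0.20, -0.08 and -0.15. Sarcomere scaffold genes lay at 0.45 in library 3, with 5 of 9 genes highest there, but did not stand apart from library 1 singly (percentile 96.9). MYOM2 was listed at 615, 899 and 1215 FPKM and TMOD4 at 231, 9.68 and 197 FPKM.

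Library 3 had low values for ribosomal, macrophage and adipocyte genes. Ribosomal protein genes lay at a relative log2 deviation of -0.43, with 34 of 37 genes lowest in library 3, and 29 after median-of-ratios scaling. RPL39L, which entered the list through a synonym, was listed at 1640, 1736 and 1063 FPKM. Macrophage and monocyte genes lay at -0.89 in library 3, with 8 of 8 genes lowest there. CD74, of antigen presentation, was listed at 325, 270 and 136 FPKM and CTSS, a lysosomal protease, at 21.3, 26.9 and 9.16 FPKM. The same list stood apart upward in libraries 1 and 2 (0.49 and 0.41), but without library 3 these values were 0.02 and -0.02, while library 1 lay at 0.95 without library 2 and library 2 at 0.86 without library 1. The call of library 1 was lost with no filter (0.32) and with pseudocount 0.1 (percentile 99.1), and that of library 2 with curated transcripts only (0.35, percentile 96.8). Adipocyte genes lay at -0.73 in library 3, with 8 of 10 lowest there, and at 0.79 in library 1. FABP4, a lipid chaperone, was listed at 113, 71.3 and 15.5 FPKM and G0S2, an inhibitor of lipolysis, at 93.6, 42.7 and 27.4 FPKM. The call of library 1 did not stand against library 2 alone (0.43, percentile 99.4). Immediate early genes were also low in library 3, at -1.09, and at -0.45 without library 1.

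Inflammation and innate immunity genes lay at 0.57 in library 1 and -0.34 in library 3, with 9 of 14 genes highest in library 1 and 11 of 14 lowest in library 3. STAT3 was listed at 57.4, 31.3 and 32.2 FPKM and NFKBIA, an inhibitor of NF-kappaB, at 31.0, 24.3 and 12.2 FPKM. Neither call stood against library 2 alone, where library 1 lay at 0.34 (percentile 99.3) and library 3 at -0.25 (percentile 1.95). With no filter on low values, library 1 lay at 0.25 and its call was lost, and without library 2, library 3 lay at -0.61. Fibroblast genes lay at 0.86 in library 2, above each other library singly, but at 0.42 without library 1 and 0.48 with no filter. COL1A2 was listed at 80.8, 205 and 153 FPKM and THY1 at 15.1, 32.0 and 8.61 FPKM. Endothelial genes lay at -0.43 in library 2, with 8 of 10 lowest there, but at percentile 0.53 against library 1 alone. PLVAP was listed at 57.0, 30.1 and 30.8 FPKM. Clock genes lay at -0.56 in library 2, at -0.34 with no filter, and at -0.36 (percentile 0.55, no call) against library 3 alone and -1.09 against library 1 alone.

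The lists named for the exposure did not stand apart. Genes of ammonia and amino acid nitrogen metabolism lay at relative log2 deviations of -0.12, -0.02 and 0.19 in libraries 1 to 3, and purine and uric acid genes at -0.26, 0.11 and 0.06. Among single members, GLUL, which fixes ammonia as glutamine, was listed at 108, 31.1 and 23.4 FPKM, and ADSL at 668, 684 and 449 FPKM. Neither was called by the spread test, which also called no simulated gene shifted by a log2 of 2 or 4. That does not show that they varied little. Fast contractile genes lay at -0.40, 0.16 and 0.04 and slow contractile genes at -0.37, 0.28 and 0.02. Glycolysis genes lay at -0.12, -0.10 and 0.13, with LDHA at 11997, 11033 and 14248 FPKM. The remaining lists that did not stand apart were glycogen metabolism, fatty acid oxidation, lipid synthesis, muscle protein breakdown, growth signalling, myogenic genes, heat shock, unfolded protein response, oxidative stress defence and apoptosis. Among their members, UCP3, a mitochondrial carrier, was listed at 481, 146 and 110.2 FPKM, the cardiac actin ACTC1 at 276, 2046 and 2608 FPKM, and the small heat shock protein HSPB1 at 1056, 2926 and 1545 FPKM. ATF4, a stress-response transcription factor, was listed at 480, 445 and 468 FPKM.

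**Figure D2:**
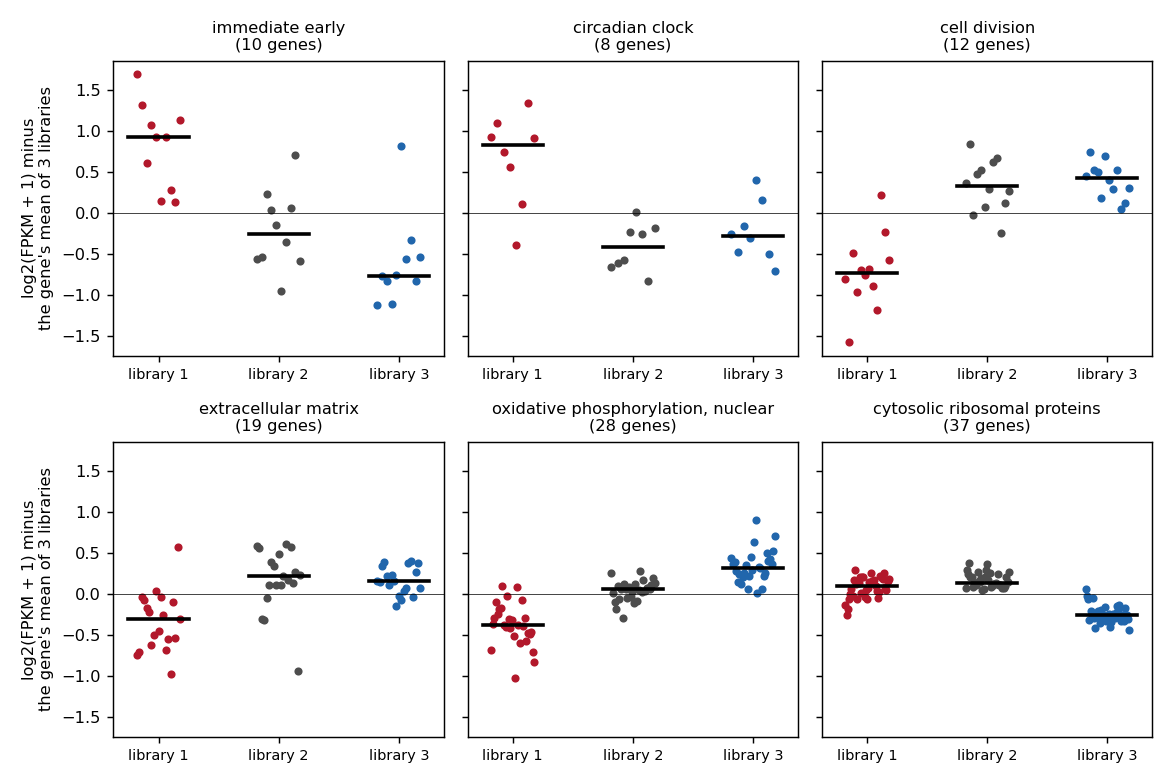
Members of 6 gene lists, each point 1 gene in 1 library, as log2(FPKM + 1) minus the gene's mean over 3 libraries (y axis), with black bars for the median of a list in a library. Of immediate early genes 8 of 10 are highest in library 1, of cell division genes 11 of 12 are lowest there, and of oxidative phosphorylation genes 27 of 28 are highest in library 3.

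The spread of whole lists was compared in the same way. Immediate early, cell division, adipocyte, circadian clock, fibroblast, extracellular matrix, inflammation and macrophage genes had a larger SD between libraries than matched random lists. These were 8 lists, where chance would give 0.28 if genes were independent. All 8 also stood apart in at least 1 library above. Both measures use the same values, so this is not a separate result. The median SD of log2 level was 0.87 for immediate early genes against 0.24 for random lists, and 0.67 for cell division genes against 0.27. None stood apart downward. Ribosomal protein genes had a median SD of 0.24 against 0.26, and unfolded protein response genes 0.17 against 0.24. Without library 1, 4 lists stood apart.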

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

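The scalings between libraries, curated transcripts only, single transcripts, 5 bins for spread, pseudocount 0.1 for single genes, and libraries left out for the list calls were chosen after seeing the data. Of the 24 list calls, all kept direction and side with 5 bins, median-of-ratios scaling and equal totals, 22 did with no filter (inflammation and macrophage genes in library 1 did not) and with pseudocount 0.1 (matrix genes in library 3 and macrophage genes in library 1 did not), and 21 with curated transcripts (citrate cycle and matrix genes in library 3 and macrophage genes in library 2 did not), and no call changed direction in these 6 settings. The number of calls ranged from 22 to 27 there, and from 12 to 20 with 1 library left out. The latter are counts over 2 libraries per list, which are mirror images, and do not compare with counts over 3. The low value of 12 came without library 3. With 1 library left out, extracellular matrix genes in library 3 ranged from -0.17 (without replicate 1) to 0.50, cell division genes in library 2 from -0.063 (without replicate 1) to 1.14, and macrophage genes in library 2 from -0.019 (without replicate 3) to 0.86. These reversals follow from the construction, since the library left out had set the mean. The number of lists with large spread ranged from 4 to 9 with 1 library left out. The number of genes with excess spread was 0 in every other setting and ranged from 0 to 31 with 1 library left out. The cause was not tested. Values above 0 in all 3 libraries were listed for 27883 transcripts against 8594 named genes, which counts a different feature. The share of all lists moved by less than its SD, and 3 to 5 paralog ratios were called. Not run, since the tables hold no counts or only 1 unit, were the count-based normalizations, filters, dispersion tools and thinning, and counts against length-scaled values. Leaving out mitochondrially encoded genes was not run, since none was matched. No paired analysis was possible because there is only 1 group. Unknown depth limits what can be said of low genes, cell division genes among them.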

Other observations

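Tests of the lower share of muscle fibres and of slow fibres were chosen after the values they use had been seen. The glucocorticoid and sterol lists were written before their members' values were seen, but after FKBP5, SESN1, SOCS3, INSIG1 and the list values of library 1 had been seen, so they are not independent of the pattern. Members were at first also matched through synonyms, and this was narrowed to symbols after that run. Both versions are given for the glucocorticoid list, and for the sterol list they hold the same genes.

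Sterol synthesis genes, a group outside the fixed lists, were low in library 1. Of 11 genes scored, 8 were lowest in library 1, with a relative log2 deviation of -1.11, against 0.29 in library 2 and 0.56 in library 3. LSS was listed at 1.01, 6.37 and 5.53 FPKM in libraries 1 to 3, while FDFT1 went the other way at 46.0, 19.3 and 21.1 FPKM. Of 10 genes that glucocorticoids or fasting induce, 8 were highest in library 1, among them KLF9 at 16.0, 7.73 and 8.75 FPKM and BCL6 at 14.9, 6.88 and 3.43 FPKM. CDKN1A did not follow, at 135, 531 and 117 FPKM, nor did GADD45A, at 53.9, 62.1 and 53.0 FPKM. ANGPTL4 and ARRDC2 did not pass the filter and were lowest in library 1. They were listed at 0.19, 0.70 and 0.75 FPKM and at 0.17, 0.92 and 2.01 FPKM. These members were chosen after their values were seen.

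For the 8 lists that stood apart in library 1, a lower share of muscle fibres was considered after their values had been seen. The markers of other cell types did not rise alike there, which does not decide on that cause. The adipocyte list exceeded the fibroblast list by a log2 of 1.30 in library 1 (95% bootstrap interval over genes, which are not replicates, 0.24 to 2.25). That comparison cannot decide on a lower share of fibres with more fat, which would give the same result. Fast and slow contractile genes lay low in library 1 without standing apart (-0.40, percentile 2.25, and -0.37, percentile 2.74). Macrophage genes (0.49) and endothelial genes (0.32, percentile 98.91, no call) lay high there, and fibroblast genes low (-0.49, no call). A lower share of fibres with unequal rises of other cell types stays open. For a glucocorticoid or fasting type response, the 10 genes lay at the 99.99th percentile of matched random lists in library 1 (relative log2 deviation 0.64). With synonyms also matched, 12 genes lay at the 100th (0.59). The same 10 genes lay at -0.11 in library 2 and at -0.60, percentile 0, in library 3, so library 3 stood apart on the other side. For lower sterol drive, the sterol genes lay at percentile 0 in library 1, though they stood apart upward in library 3 (0.56, percentile 99.99). The 10 genes and the sterol genes are not members of the 8 lists. Whether either response accounts for any of the 8 was not tested. The fixed lipid synthesis list lay at -0.02 (percentile 43.2) in library 1. Feeding, sampling time and handling are not in the labels, so neither explanation was tested against a group. A division of reads between named and unnamed isoforms stays open: 100% of the 8 still stood apart with curated transcripts only, but that setting left their values at 0.97 to 1.16 times the reported ones and does not undo such a division.

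The adipocyte list was high in library 1, and more fat tissue in that piece is a candidate explanation that cannot be told apart from regulation within cells. Of 5 adipocyte genes, 4 lay above the matched random lists, FABP4 and PLIN1 among them. ADIPOQ, the adipocyte hormone, did not, at 38.4, 36.1 and 46.9 FPKM. PLIN1, ADIPOQ and LPL lie outside the naming rule and were chosen after their values were seen. Of the list's members FABP4 and LPL are also in the fatty acid list, and muscle fibres or vessels can express them.

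TNNC1, the slow and cardiac troponin C, stood close to TNNC2 in every library. Slow fibres in the piece are argued against as the source, since the smallest log2 ratio of TNNI2 to TNNI1 and TPM1 to TPM3 in any library was 8.13. Of the 12 slow list genes matched, CASQ2 was also abundant, with a mean of 1558 FPKM, while the other 10 had means of 35.7 FPKM or less. No fast partner of CASQ2 was matched, since the gene table gives CASQ1 as a synonym of this same gene. Its level therefore does not speak for or against slow fibres. The transcript's sequence was not checked here, so an error in naming and reads shared with TNNC2 stay open.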
